A study of Drosophila melanogaster with 4 samples.

How the data were processed

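Chromatin of 14 to 16 h Oregon-R embryos was crosslinked with formaldehyde and immunoprecipitated with an antibody against HP4 (Q4072), per the labels' protocols. The 4 libraries form 2 groups by title, HP4 ChIP with replicates 1 and 2 and input with replicates 1 and 2. Each input is labelled as having served 1 ChIP library, and no value of an input library was used here.

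Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The region caller, its threshold, its window size, the treatment of reads that map to several places and the way the replicates were combined are not given in the sources used here. The authors deposited 3 lists of regions of significant enrichment, per the file headers in FlyBase release 5 coordinates, with 1 score per region. The deposited score is the authors' own value for each region and its scale is not stated. Equal scores (tolerance 1e-09) recur within each list, and among the distinct recurring values of replicate 1, 58 pairs differ by 1 within 1e-06 and 0 pairs differ by 0.9 or 1.1; the same counts are 51 and 0 in replicate 2 and 63 and 0 in the combined list. That spacing is what a log2 ratio of whole counts would give. Scores are used here to describe, rank or filter regions within a list, and between lists only to correlate matched regions and to set the replicate scores of named regions beside the combined score, which assumes a like scale in each list. The narrowest regions are 1301 and 1302 bp in the replicate lists and 1001 bp in the combined list, so the lists were not made with one common minimum. No depth per library was used, and errors are the spread between replicates, the spread between 1 Mb bins where stated, or counting intervals.

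Sequence lengths came from the file headers. Of the sequences named there, 13 hold regions and Uextra holds none in any list; Uextra was left out of all densities. Repeated sequence is common in the Het scaffolds and U, so coverage there depends on how the authors placed reads that fit more than 1 position. The gene table at hand is of genome release 6 with no release 5 coordinates, so no region was assigned to a gene, and the planned counts of genes, gene lists and gene parts were not made.

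Regions were read with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plotted with matplotlib 3.10.9. Coverage is the number of bases in regions divided by sequence length. Overlap means at least 1 shared bp. Replicate overlap was tested against 1000 circular shifts of replicate 2 within each sequence (one-sided). Density per sequence was tested by 10000 rotations of all regions along the sequences laid end to end (two-sided), with Benjamini-Hochberg adjustment over 13 sequences. Centromere-proximal density was tested by 10000 circular shifts within each arm (two-sided); the proximal end is the right end of 2L, 3L and X and the left end of 2R and 3R. These p-values concern the placement of regions, not variation between embryos, since 2 replicates allow no test between them. Simulated lists were made of single regions spread without local clustering. A density planted 10 times higher on chromosome 4 was found as 9.91 times the mean of the large arms (7583 regions). One planted 5 times higher in the proximal 1 Mb was found as 4.98 times (13906 regions). The real regions are clustered, so these lists do not show what excess the density rotations could detect in them. The overlap and proximal tests were also checked on lists made from the 2703 replicate 1 regions: with no shared position, 8 of 100 simulated pairs passed the overlap test at 0.05 and 2 of 100 shifted lists passed the proximal test, and with 50% of regions kept in place 20 of 20 pairs passed.

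Apart from the 2 islands on 2L and 2R and the widest distal regions, which were chosen after their values were seen, the text names regions by a rule fixed before the data were examined: the 10 highest-scoring and the 5 widest combined-list regions overlapped by both replicates, the highest-scoring such region of each sequence, and the 3 highest-scoring regions of each replicate with no overlap in the other. The design, the tests and most alternatives were also fixed before the data were examined. Alternatives were merging of close regions, the upper 50% of each list by score, stricter overlaps, uniform placement, other proximal windows, region counts in place of covered bases, spans in place of full lengths, each replicate left out, and the combined list. The comparison of Het scaffolds with large arms was planned, but its expression as a ratio and the alternatives for that ratio, the distal arm (more than 3 Mb from the proximal end of a large arm), the profiles in 0.25 and 0.5 Mb steps, the independent placement of regions over all sequences and the proximal ratio without 3R were chosen after seeing the data.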

Results

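HP4 was profiled by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in wild-type Oregon-R embryos of Drosophila melanogaster staged at 14 to 16 h. HP4 is a chromatin protein named for heterochromatin, the compact and repeat-rich part of the genome, and is known as a partner of the heterochromatin protein HP1. The series holds 2 ChIP libraries and 2 input libraries, the inputs being chromatin DNA that was not immunoprecipitated. The deposited values are 1 list of enriched regions for each ChIP library and 1 combined list for the replicate set, all in coordinates of FlyBase release 5. Read depths are unknown from these lists, so the counting error behind each region could not be computed. Nothing in the labels says whether the replicates came from separate embryo collections, so the spread between them may be technical. Means are given ± SD over the 2 ChIP replicates (n = 2).

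The first question was how much of the genome carried HP4 and on which sequences. Most HP4-covered sequence lay outside the large chromosome arms. The 5 Het scaffolds, the heterochromatic sequence assigned to chromosomes 2, 3 and X outside the continuous arms, were covered over 51.9% ± 0.775 of their length. The 5 large arms, mostly gene-rich euchromatin, were covered over 2.53% ± 0.0725, which put the Het scaffolds 20.6 ± 0.283 times higher. Chromosome 4, the small dot chromosome that is known to be rich in HP1, was intermediate at 14.5% ± 3.55, and at 32.3% in the combined list. Sequence assigned to no chromosome (U) reached 36.1% ± 0.906 and the Y scaffold (YHet) 27.3% ± 0.835. Replicate 1 held 2703 regions over 11.4 Mb and replicate 2 held 2674 regions over 11.8 Mb, with median widths of 2622 and 2700 bp. Of the covered bases, 40.1% ± 0.433 lay on the Het scaffolds, 31.4% ± 0.0195 on U and 26.0% ± 0.0775 on the large arms.

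Individual sequences differed by far more than the replicates did. Among the Het scaffolds, 3LHet was the most covered at 58.6% ± 0.888, followed by 3RHet at 55.6% ± 0.695, 2RHet at 47.0% ± 0.994, 2LHet at 40.6% ± 1.17 and XHet at 24.2% ± 0.353. Among the large arms, 2R had 4.96% ± 0.0517 of its length covered, 3L 3.99% ± 0.148, 2L 2.51% ± 0.0291 and X 1.27% ± 0.0799. The right arm of chromosome 3 (3R) was the least covered sequence, at 0.416% ± 0.0512, although 3RHet was among the most covered. Chromosome 4 was the sequence on which the covered percentage differed most between replicates, with 59 regions over 12.0% of its length in replicate 1 and 80 regions over 17.0% in replicate 2. Its regions also scored low, with a median score of 0.72 ± 0.03 against 1.15 ± 0.03 on the Het scaffolds and 1.58 ± 0.03 on U.

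A position test, in which all regions were rotated together along the sequences laid end to end (10000 rotations, two-sided permutation test), placed 0 of 13 sequences past an adjusted p of 0.05. At an unadjusted permutation p under 0.05 there were 2 sequences, 3R below the genome mean of 8.28% (p = 0.017, adjusted p = 0.18) and 3LHet above it (p = 0.028, adjusted p = 0.18). Rotation keeps neighbouring regions together. With the sequences in chromosome order, the Het scaffolds adjoin the dense proximal ends, so a rotated short sequence can fall wholly within a dense block. The short 2LHet, 40.6% covered, had p = 0.20 and chromosome 4 had p = 0.35 (permutation test). The test thus has little power for short sequences, and its result does not argue against the Het scaffold excess. By rotation, regions per Mb and the combined list each placed 2 sequences past the threshold, 3R (adjusted p = 0.025 and 0.026) and U (adjusted p = 0.025 and 0.036, permutation tests). When each region was instead placed independently, 13 of 13 sequences passed, a test that treats neighbouring regions as unrelated.

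**Figure D1:**
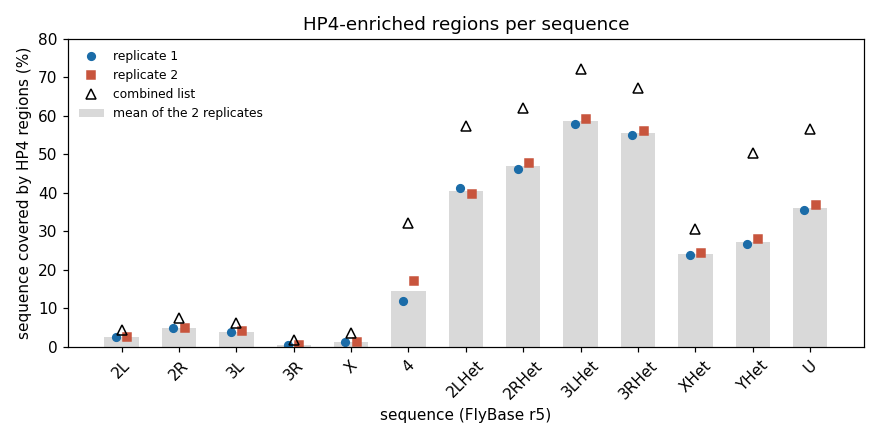
Percentage of each sequence covered by HP4-enriched regions in FlyBase release 5 (vertical axis) for the 13 sequences that hold regions (horizontal axis). Grey bars are the mean of the 2 replicates, filled circles and squares the replicates, and open triangles the combined list; the Het scaffolds stand between 24.2% and 58.6% and the large arms at or below 4.96% in the replicate means.

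The second comparison asked whether HP4 on the large arms was concentrated near the centromere. It was on 2L, 2R and 3L, where the centromere-proximal 1 Mb was covered over 42.6% ± 0.0689, 62.6% ± 1.06 and 58.4% ± 0.723 of its length. The remaining parts of those arms were covered over 0.687% ± 0.0273, 2.10% ± 0.00182 and 1.68% ± 0.124. On X the proximal 1 Mb reached 12.0% ± 0.315 against 0.771% ± 0.0689 elsewhere, and on 3R it reached 0.914% ± 0.0467 against 0.397% ± 0.0548. Over the 5 arms together, the proximal 1 Mb was 32.4 ± 1.31 times as densely covered as the rest, and 4.20% of the arm length held 58.7% ± 0.980 of the covered arm bases. The ratio was 16.7 in the combined list, where the share was 42.3%, 17.6 for regions per Mb and 19.9 with a proximal window of 0.5 Mb.

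A permutation test by circular shifts of the regions within each arm gave p = 0.0002 for the pooled ratio, the smallest value that 10000 two-sided shifts can give. By arm, this permutation test with Benjamini-Hochberg adjustment over 5 arms gave adjusted p = 0.012 for 2L, 0.012 for 2R, 0.038 for 3L, 0.080 for X and 0.21 for 3R. The calls on 2L, 2R and 3L were lost at an adjusted p of 0.064 each when the proximal window was 0.5 or 2 Mb, although the ratios stayed large, at 44.3, 17.2 and 20.8 with 0.5 Mb and 32.3, 72.9 and 95.4 with 2 Mb, against 61.9, 29.7 and 34.8 with 1 Mb. The 2R call was also lost for regions per Mb (adjusted p = 0.076) and the 3L call in the upper 50% by score (0.095), while 3R passed in the combined list (0.011, permutation tests).

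The dense domains ended within a short distance. On 3L coverage stayed between 48.9% and 61.0% per 0.25 Mb window over the first 1.5 Mb from the proximal end and was 4.44% ± 0.0800 in the next window. On 2R it stayed between 48.1% and 78.8% over the first 1.5 Mb and was 9.76% ± 0.703 in the next. On 2L it lay between 46.1% and 68.4% over the first 0.75 Mb and was 9.50% ± 1.60 in the next. X differed in shape: the first 0.5 Mb was nearly free of regions, with 0.591% and 0.611% covered in replicates 1 and 2, and the signal lay between 0.5 and 1 Mb from the end, with 22.9% and 23.8% covered. With a proximal window of 0.5 Mb the X ratio therefore fell below 1, to 0.467.

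**Figure D2:**
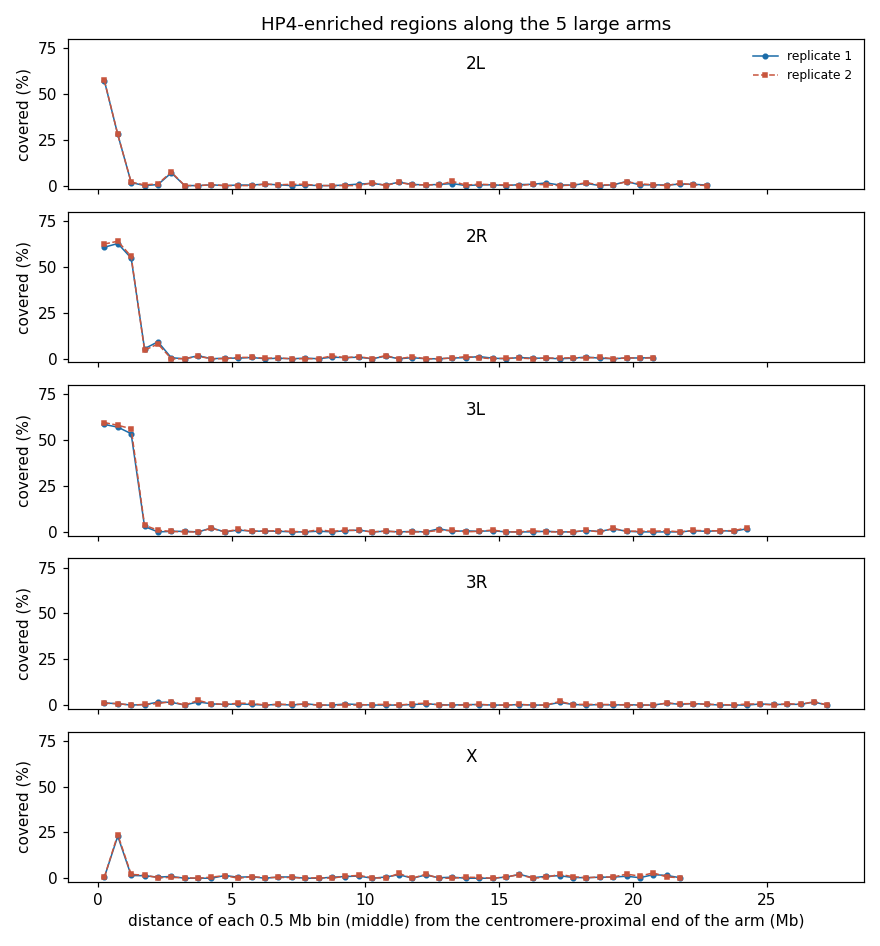
Percentage of each 0.5 Mb bin covered by HP4-enriched regions (vertical axis) against the distance of the bin from the centromere-proximal end of the arm in Mb (horizontal axis), for 2L, 2R, 3L, 3R and X, with replicate 1 as a solid line and replicate 2 as a dashed line. The bins next to the proximal end exceed 50% on 2L, 2R and 3L, the X signal lies in the bin between 0.5 and 1 Mb, and 3R shows no such peak.

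Outside these proximal domains 2 shorter islands of HP4 regions stood out. Of the 216 bins of 0.5 Mb lying more than 2 Mb from the proximal end of an arm, 2 were over 5% covered in both replicates, and none of the other 214 exceeded 2.93% in either. The first was on 2L, at 7.13% ± 0.317, where 3 replicated regions of the combined list lay between 20099667 and 20198097 and the widest spanned 23.4 kb from 20174744 to 20198097. The second was on 2R, at 8.65% ± 0.840, where 12 replicated regions lay between 2146954 and 2347734. Both intervals were chosen after their values were seen and were not tested.

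The third comparison was between the replicates. HP4 regions recurred at the same places: 82.8% of the replicate 1 regions overlapped a replicate 2 region by at least 1 bp, and 79.7% of the replicate 2 regions overlapped one of replicate 1. Random circular shifts of replicate 2 within each sequence gave 48.0% and 47.8% on average, and the Jaccard index of the covered bases was 0.717 against 0.204 under shifts (p = 0.001, one-sided permutation test, the smallest value that 1000 shifts can give). Overlap was highest on XHet (Jaccard index 0.911, from 7 and 4 regions), 3RHet (0.830) and 3LHet (0.806). It was lower on YHet (0.531), on X (0.505), on 4 (0.419) and on 3R (0.398). The index that arises by chance rises with coverage and was not computed by sequence. Replicates 1 and 2 covered 55.1% and 56.1% of 3RHet but 0.380% and 0.452% of 3R. This order therefore does not rank the sequences by agreement beyond chance. In the distal arms, more than 3 Mb from the proximal ends, 54.2% of the 238 replicate 1 regions and 48.4% of the 258 replicate 2 regions overlapped, against 1.09% and 1.00% under shifts (p = 0.001, permutation test). Across 2237 matched regions the authors' scores correlated with a Spearman rho of 0.836 and a Pearson r of 0.799, a correlation across regions, which are not independent replicates. The 466 replicate 1 regions and 543 replicate 2 regions with no partner were narrower, with median widths of 1578 and 1669 bp against 3158 and 3273 bp for those with a partner.

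All 10 of the highest-scoring regions of the combined list that both replicates overlapped were on U, with scores of 2.80 to 3.46 and widths of 2113 to 5378 bp. The top one ran from 4991487 to 4993915 and scored 2.85 in replicate 1 and 4.53 in replicate 2. Those starting at 7900693 and 6561161 had exactly the same replicate 2 score, 3.53. Equal scores can arise from ratios of few reads, which was not tested for these regions. Repeated sequence is common on U, so their calls also depend on how reads that fit several positions were placed. The 5 widest replicated regions scored only 1.21 to 1.44. They were 84.4 kb on 3RHet from 1496294 to 1580711, 60.9 kb on 2R from 816080 to 877011, 60.4 kb on 3LHet from 380268 to 440632, 58.2 kb on 3RHet from 1282920 to 1341153, and 57.2 kb on U from 373027 to 430255. Each was covered over at least 84.3% of its length by the regions of either replicate.

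The best-scoring replicated region of each large arm lay in the proximal domain for 4 arms. These were on 2L from 22711611 to 22722711 (score 1.97), on 2R from 180282 to 188594 (1.97), on 3L from 24371012 to 24375962 (2.09) and on X from 21758757 to 21764386 (2.58). On 3R it ran from 2732882 to 2735108 and scored 2.12, with 1.72 in replicate 1 and 2.50 in replicate 2. On chromosome 4 it was a 16.8 kb region near the left end of the sequence, from 8065 to 24827, with a score of 2.29. The best on 2RHet was from 1995182 to 1999986 (2.62). The replicates shared no base in it: the replicate 1 region ran from 1997076 to 1999400 and the replicate 2 region from 1995243 to 1997017, as in 16 of the 1641 combined-list regions that both replicates overlapped. The best was on 3LHet from 515459 to 518008 (2.08), on 3RHet from 1053173 to 1057880 (1.91) and on 2LHet from 307011 to 319397 (1.67). XHet had its best region from 154989 to 184540 (1.45) and YHet from 302214 to 305033 (2.06). The best regions of X and YHet had exactly the same replicate 2 score, 2.36. Whether ratios of few reads gave this equal score was not tested. Some high scores had no partner in the other replicate. In replicate 1 these were the 2RHet region just named (4.05), on U from 7239075 to 7240715 (3.94) and on 3LHet from 29141 to 31123 (3.81). In replicate 2 they were on U from 2727909 to 2729875 (4.06), on 4 from 613827 to 615413 (3.82) and on U from 9774209 to 9775962 (3.68).

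The last comparison set the combined list against the replicates. The combined list held 4366 regions over 17.6 Mb, and it contained 98.4% of the replicate 1 regions and 99.0% of those of replicate 2. Both replicates overlapped 37.6% of its regions (Wilson 95% interval 36.2% to 39.0%, counting error only), which carried 74.7% of its covered bases. The share of regions was 61.4% in the upper 50% of the list by score. It did not keep rising with score: it was 49.0% among the 437 highest-scoring regions and 50.9% among 436 regions of middle score. Of the whole list, a further 17.9% were overlapped by 1 replicate and 44.5% by neither. The added regions lay mostly on the arms. Neither replicate overlapped 76.8% of the 1340 distal-arm regions (interval 74.5% to 79.0%). The share was 20.4% of the 808 Het scaffold regions (17.8% to 23.3%), 29.3% of those on U and 42.6% of the 148 on chromosome 4. Overlap by chance is likelier where replicate regions cover more sequence, 51.9% of the Het scaffolds against 2.53% of the large arms. No chance share was computed by class, so these shares do not compare the reliability of the calls between classes. On 3R the combined list held 331 regions against 54 and 62 in the replicates, and on X 413 against 101 and 110. Regions overlapped by neither replicate had a median width of 1208 bp and a median score of 0.58, against 5354 bp and 1.21 for regions overlapped by both. The Het scaffolds were 14.4 times as densely covered as the large arms in the combined list.

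**Figure D3:**
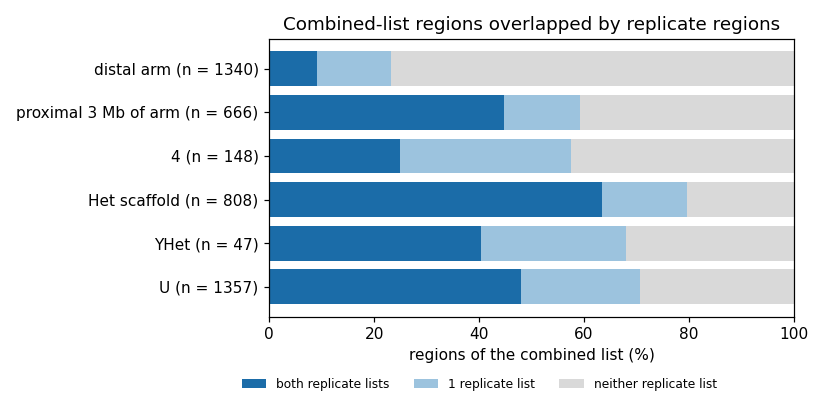
Share of combined-list regions (horizontal axis, percent) that overlap regions of both replicate lists, of 1 or of neither, for 6 classes of sequence (vertical axis, n = number of regions). Distal arm means more than 3 Mb from the proximal end of a large arm. Of its regions, 9.18% overlap both replicates. The share is 63.4% on the Het scaffolds, where overlap by chance is likelier because replicate regions cover more of the sequence.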

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

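Replicate overlap and the pooled proximal excess kept their direction and stayed past the threshold under every alternative run for them, the proximal ratio running from 16.7 in the combined list to 41.9 with a window of 2 Mb. The distal X excess of 3.16 kb per Mb lost the threshold when the largest difference of any arm was tested over rotations of the bins (p = 0.098, permutation test; 4.0e-05 to 0.029 in the other alternatives). The replicate overlap in the distal arms, all settings of the distal X excess, the alternatives for the Het scaffold to arm ratio, the independent placement of regions over all sequences and the proximal ratio without 3R were chosen after the results were seen. No paired analysis was possible because no value per input library was used here. Mean regions per replicate fell from 2688.5 to 1344.5 in the upper 50% by score, and the filter at 200 bp removed no region. Both outcomes followed from the settings, since the narrowest replicate region was 1301 bp, and they say nothing about robustness. The share of combined-list regions overlapped by both replicates was 32.0% when 50% of the region had to be covered. It was 61.4% in the upper 50% by score but 49.0% among the 437 highest-scoring regions. The count of sequences past the rotation test was 0 in the main test, 2 for regions per Mb (3R and U), 2 in the combined list (3R and U) and 13 with independent placement. The Het scaffold to arm ratio was 14.4 in the combined list and 27.2 in the upper 50% by score. Spearman rho of the scores was 0.869 for one-to-one matches, 0.878 for reciprocal overlap of 50% and 0.751 on 2L, 2R, 3L, 3R, 4 and X. Without replicate 1 or replicate 2 in turn, the Het scaffold to arm ratio ran from 20.4 to 20.8. Against the mean of the 6 main sequences alone, 2R (49.6 kb per Mb) and 3L (39.9 kb per Mb) turned from below to above the mean, and in the upper 50% by score chromosome 4 turned from above to below the mean of all 13 sequences at 33.1 kb per Mb. The proximal ratio of X turned to 0.467 with a window of 0.5 Mb, and that of 3R to 0 in the upper 50% by score; in the combined list the 3R ratio was 2.87 with an adjusted p of 0.011 (permutation test; 0.17 to 1 in the other alternatives). The causes of these changes were not tested except where stated. The 2R ratio also missed the threshold when regions were counted (adjusted p = 0.076; 0.0080 to 0.064 otherwise), and the 3L ratio in the upper 50% by score (adjusted p = 0.095; 0.0020 to 0.064 otherwise, permutation tests). Of 54 scores of named regions taken from 1 replicate alone, 35 lay within the replicate SD of the combined score. That SD comes from the same replicate scores and widens as they disagree, so this count does not measure agreement. Gene-based alternatives were not run, for lack of a release 5 annotation, and lengths from outside the files were not needed because the headers give them. Depth is unknown, so whether a region missing from 1 list was below detection cannot be said.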

Other observations

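All tests in this part were chosen after the data had been seen, and only the test of tied scores by width and the test of regions found in the combined list alone, on 1 Mb bins defined after seeing the data, were chosen before their own results were seen. The distal arms, away from centromeric heterochromatin, carried scattered HP4 regions, and X carried more than the autosomes. Distal X bins of 1 Mb had 7.48 kb covered on average (SD 4.72 over 19 bins), against 4.32 kb on the autosomes (SD 3.02 over 83 bins), 1.73 times as much. The autosome arms had 5.11 kb on 2L, 4.71 kb on 3L, 4.29 kb on 2R and 3.35 kb on 3R. The difference of 3.16 kb was tested by permuting bins (100000 permutations, two-sided p = 0.00080), but X had been picked after its value was seen. The largest difference of any arm gave p = 0.0017 when bins were permuted and p = 0.098 when they were rotated along the arms (102 rotations, permutation test), which keeps neighbouring bins together, so chance placement was not excluded. It was 3.37 kb without replicate 1, 2.96 kb without replicate 2 and 8.92 kb in the combined list, where X was 1.51 times as covered.

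The widest replicated distal region was at the tip of X, 16.6 kb from 2010 to 18585, with 6.45 kb covered in replicate 1 and 8.69 kb in replicate 2. No list held a region in the last 20 kb of the distal ends of 2L, 2R, 3L or 3R. Within 100 kb of the end, 3L had 8.61 kb and 9.34 kb covered in replicates 1 and 2. Other wide distal regions were on 3R from 26899927 to 26908040 (8.11 kb) and from 3521675 to 3529481 (7.81 kb), on X from 1521799 to 1529474 (7.68 kb) and on 2L from 3251876 to 3259434 (7.56 kb).

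The combined list has 1942 regions, most of them on the arms, that neither replicate list holds. A shorter window or looser threshold in the combined call is a candidate explanation. Of these regions, 60.7% were narrower than the narrowest region of either replicate list. Their median width and score also lay below those of replicated regions. Regions that neither replicate called could be narrower and lower in score for other reasons too, so these values do not single out this explanation. Weak HP4 sites that gather where replicated sites do were tested across 102 distal 1 Mb bins, and the Spearman rho of covered bases was 0.0496 (permutation p = 0.62; Pearson r 0.0870, p = 0.38, or 0.0667 without the 2 bins farthest from the median). By arm rho ran from -0.470 on 3R (24 bins) and -0.103 on 2R to 0.140 on 3L and 0.148 on X, and these values neither show nor rule out such sites. Whether the added regions are weak binding or noise stays open.

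Some of the highest scores of the combined list lie in narrow regions. Of the 437 regions in its top 10% by score, 97 were under 1500 bp and 182 were 3000 bp or wider. Narrow regions were not over-represented there, since the lower width quartile of the whole list was 1242 bp. Both replicates overlapped 0 of the narrow group and 86.3% of the wide group. Replicate regions were at least 1301 bp wide, and the combined list held 99.1% and 99.3% of the bases of replicates 1 and 2. A combined region under 1500 bp thus had little room for a region of each replicate. The value of 0 therefore does not measure how reliable the narrow regions are. Scores shared exactly with another region made up 97.9% of the narrow group and 17.6% of the wide group (Fisher's exact test, two-sided, p = 1.36e-43), which suggests that the narrow regions rest on ratios of few reads. Whether the narrow regions include strong sites that the replicate lists missed was not tested. The score alone may therefore be a poor guide to the strength of narrow regions.

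The proximal 1 Mb of 3R had 0.914% of its length covered, against 42.6% or more on 2L, 2R and 3L. Absence of HP4 from the pericentric chromatin of the right arm of chromosome 3 is argued against by 3RHet, of which 55.6% was covered, above 2LHet and 2RHet in both replicates. It remains possible that the assembled 3R sequence begins outside heterochromatin, so that no dense domain could appear there; the repeat content that would decide this was not analysed here.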
